A study of Homo sapiens with 2 samples.

How the data were processed

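Total RNA from HCT116 cells transfected with a control siRNA or a PHF5A siRNA was extracted with Trizol and made into libraries with the TruSeq Stranded Total RNA kit, per the labels' protocols. There was 1 library per group and 2 in all. HISAT2 2.0.4 and Cuffdiff were used with the hg38 (GRCh38) genome, per the submitters' processing notes. The annotation release, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. The labels do not give the siRNA sequence. With 1 knockdown library, effects of the siRNA on transcripts other than PHF5A cannot be told apart from effects of PHF5A loss.

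The deposited table held, for each gene and library, a whole-number count and an FPKM value, per the file headers. The values show how the deposited FPKM was made: each is the count divided by 1 fixed length per gene and by the library's count total, since the lengths implied by the 2 libraries differed by at most 0.0241% over the 18898 genes counted in both. FPKM and counts therefore hold the same information. The table had 50869 lines. The entry of 1 gene was broken over 2 lines with values out of place, and these were left out, so 50867 gene rows were used. Of these, 26352 were 0 in both libraries. Gene type, exon number, intron length and GC content were taken from GENCODE release 29 by gene identifier, which matched 50110 rows and not 757. Positions are those of the deposited table.

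FPKM as deposited was the main measure. The log2 ratio of knockdown to control was computed with a pseudocount of 1, which understates the change of low genes. A gene counted as expressed with at least 1 FPKM in the higher library, and as higher or lower at a ratio of at least 2-fold by size alone. The control library's total was 26552789 counts and the knockdown library's 25897412, so 1 count on a gene of 1 kilobase is 0.0377 and 0.0386 FPKM. Ratios of CPM (counts scaled to the library total) carry a 95% exact conditional binomial (Clopper-Pearson) interval, and shares an exact binomial one. Where a library had 0 counts, a bound was computed from 3 counts in that library. These intervals and bounds cover counting error only, because reads are not independent molecules.

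The comparison, the measure, the thresholds, 40 gene lists and the rule for naming genes were chosen before the data were examined. For a list, the median log2 ratio of the expressed members was ranked among 10000 random lists of equal size drawn from 20 bins of mean expression. The percentile describes these 2 libraries only. The result of 1 of the lists, and genes named for it alone, are not reported here. Genes named in the text are PHF5A, the remaining SF3b members, the TEAD factors and KDM3A, and the 12 highest and 12 lowest protein-coding genes of at least 5 FPKM in the higher library with a symbol in 1 row only. Up to 4 members of each list with the largest absolute log2 ratio were named too. The ranking of genes present in both libraries, the heart muscle lists, the copies and overlapping entries and the pathway search were added after the values were seen. Genes in the structure comparison were protein-coding, and the interval of the exon difference is a bootstrap over genes.

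Alternatives were pseudocounts of 0.1 and 0.5, no filter, a minimum of 5 FPKM, centring on the median, upper-quartile scaling, rescaling to TPM, protein-coding genes alone, a 1.5-fold threshold, and CPM with a prior of 0.5. Leaving out heart muscle genes was added later. For a single gene a shift was set against the margin of its counting interval on the log2 scale, a rule chosen after a first version had been run.

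The procedure was tested on simulated data, with counts drawn for 8657 genes at the depths of the PHF5A and control libraries. It recovered 100% of 100 genes raised 4-fold and 78% of 100 lowered 4-fold, and called 1 of 8438 unchanged genes. A shifted list came out at percentile 100 and an unshifted one at 61.8. The simulation holds counting noise alone, not variation between cultures or the spread of log2 ratios seen over genes here (SD 0.63). Its list percentiles therefore do not show how well a shifted list is found in these data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Splicing itself was not analysed here, because the table is per gene.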

Results

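RNA was sequenced from HCT116 cells, an established human colorectal carcinoma line, after transfection with a control siRNA or with an siRNA against PHF5A. PHF5A is a small subunit of SF3b, the part of the U2 small nuclear ribonucleoprotein (snRNP) that holds the intron's branch point during splicing. The question was which transcripts PHF5A regulates in colorectal cancer cells. There was 1 library per group, so no difference given here has a replicate check, no test across samples was possible and no p-value is given. The control library held 26552789 counts and the knockdown library 25897412. At least 1 FPKM (fragments per kilobase, scaled to the library total) was reached by 8392 genes in the control library and by 7796 in the knockdown library. Intervals beside ratios are 95% exact intervals for counting error alone. They say nothing about variation between cultures.

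PHF5A itself (ENSG00000100410, chromosome 22, 41459717 to 41468725, GRCh38) had 367 counts in the control library and 91 in the knockdown library. Its FPKM was 9.07 and 2.31, a log2 ratio of -1.61 with 1 added to each FPKM. From counts scaled to the library total (CPM) it was 3.93-fold lower in the knockdown library (interval 3.12 to 5.0), in the direction its label states.

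Across the 8957 genes with at least 1 FPKM in the higher library, the log2 ratio of knockdown to control had a median of -0.15 and an SD of 0.63 over genes. Of these genes, 74.5% lay within 1.5-fold of the median. At least 2-fold higher in the knockdown library were 227 genes (2.53%), and at least 2-fold lower were 555 (6.2%). Among the 7677 protein-coding genes in this set the counts were 148 and 450. The surplus of lower genes depended on the scaling. Genes called higher were 29% of the calls as deposited and 49.1% (345 higher, 358 lower) after the ratios were centred on their median. They were 46.5% after upper-quartile scaling, and 7.08% (107 higher, 1405 lower) after each library was rescaled to an equal sum over genes (TPM), which moved the median to -0.47. Gene lists are therefore compared below with the median of the expressed genes. The counting interval of the ratio excluded 1 for each of the 227 higher genes and for 553 of the 555 lower ones; the thresholds had already removed most genes of low count.

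**Figure D1:**
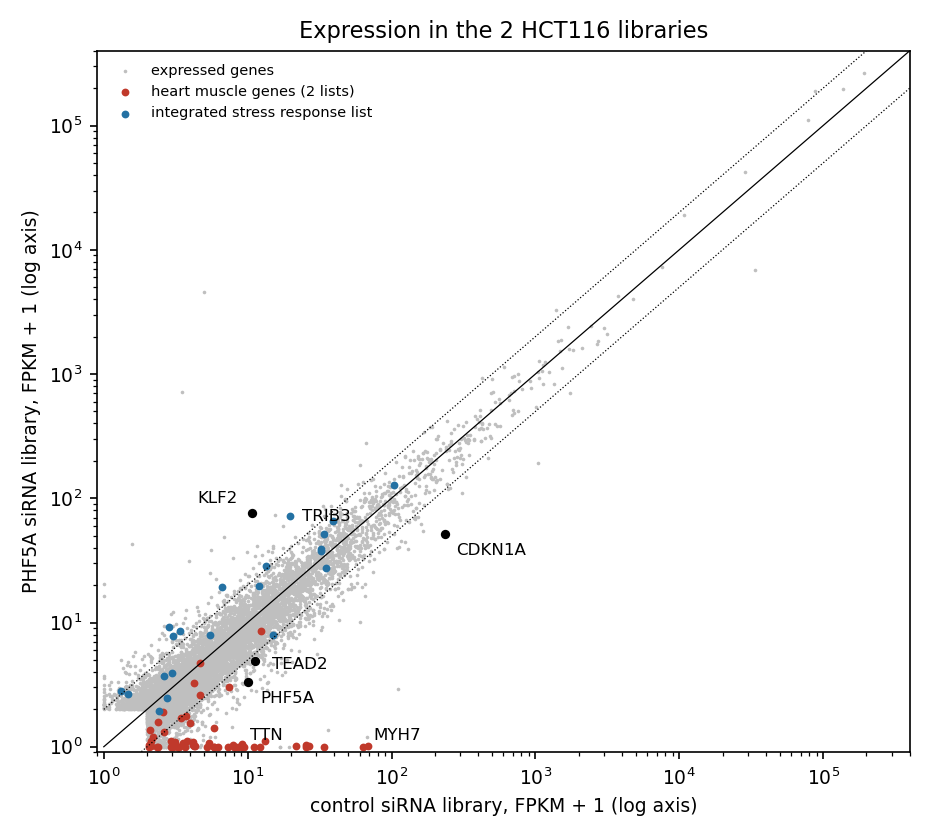
Each point is an expressed gene, with FPKM + 1 in the control library on the horizontal log axis and in the knockdown library on the vertical log axis; the solid line marks equal values and the dotted lines 2-fold differences. Most genes of the heart muscle lists lie near the bottom (MYH7 at 62.2 FPKM in the control and 0 in the knockdown library), with exceptions such as ATP2A2 (11.4 and 7.47), while integrated stress response genes lie mostly above the solid line and CDKN1A lies below it.

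Abundant small noncoding RNAs took a larger share of the knockdown library. The signal recognition particle RNA 7SL held 11% of the control counts and 15.7% of the knockdown counts. RN7SK held 2.90% and 6.32%, and RPPH1, the RNA of RNase P, held 2.62% and 3.71%. Together these made up 16.5% and 25.8% of the counts, while protein-coding genes made up 78.4% and 70.2%. The exact 95% interval of each share was at most 0.0352 percentage points wide. The FPKM denominators include these RNAs. RMRP, the RNA of RNase MRP, has 2 overlapping entries, and their summed counts were 236430 and 78580, which is 2.93-fold lower in the knockdown library.

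The 12 protein-coding genes with the lowest log2 ratios included 7 genes of heart muscle: ACTC1, MYH7, PLN, MYL7, NPPA, MYL3 and TTN. MYH7 (chromosome 14, 23412738 to 23435718) had 10058 counts in the control library and 0 in the knockdown library. Against a floor of 3 counts in the knockdown library it was 3269.9-fold lower, and by the exact interval at least 2658.8-fold lower. PLN had 1758 and 0 counts, 572-fold lower on the same floor and at least 464-fold by the exact interval. NPPA had 1011 and 0 counts, 329-fold lower on the floor and at least 267-fold by the interval. ACTC1 (chromosome 15, 34788096 to 34796139) had 9182 and 1 counts, a ratio of 0.000112 (interval 2.83e-06 to 0.000622). TTN had 65612 and 37 counts, a ratio of 0.000578 (interval 0.000407 to 0.000797). MYL7 had 2343 and 1 counts, and MYL3 had 1272 and 2. The other 5 of the 12 were MT-ATP6, MT-CO3, MT-ND4L, HIST2H4B and RP11-864I4.1, an entry with 10438 counts in the control and 30 in the knockdown library. Summed with its overlapping entries, RP11-864I4.1 had 40080 and 37140 counts, so the large difference does not hold for the locus. HIST2H4B had 3210 and 32 counts, but with its copy HIST2H4A the sum was 20053 and 17382, a log2 ratio of -0.17. Of the 555 lower genes, 49 were on 2 lists of heart muscle genes drawn up after the first look at the values. These lists together took 133725 counts (0.504%) in the control library and 7677 (0.0296%) in the knockdown library. Over all entries, expressed or not, 249 with at least 50 control counts were at least 20-fold lower, and 17 with at least 50 knockdown counts were at least 20-fold higher.

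Several of the 12 highest ratios belong to genes with a near-identical copy or an overlapping neighbour, whose reads the counting may have split differently in the 2 libraries. HIST2H2AA3 had 36 and 10253 counts, but its copy HIST2H2AA4 had 40522 and 27052, and their sum differed by a log2 ratio of -0.08. MT-ND4 had 21 and 1491 counts and MT-ATP8 had 0 and 105, while their neighbours MT-ND4L (145 and 0) and MT-ATP6 (1182 and 0) went the other way. The sums did not level out: MT-ND4 with MT-ND4L had 166 and 1491 counts (log2 ratio 3.20), and MT-ATP6 with MT-ATP8 had 1182 and 105 (log2 ratio -3.46). The 13 mitochondrial mRNAs are therefore uncertain singly. Counts on the mitochondrial chromosome as a whole were 35831 and 23740, or 1.47-fold lower in the knockdown library. The remaining 9 highest genes were PDXP, KLF2, TNFRSF6B, STK40, DBNDD1, ZBTB9, JUN, EGR1 and TRIB3. The values given for these 9 are of each gene's own entry, not summed with any overlapping ones. PDXP (chromosome 22, 37658727 to 37666934) was 10.4-fold higher by CPM (interval 9.18 to 11.8). KLF2 (chromosome 19, 16324817 to 16327874) was 7.78-fold higher (7.18 to 8.45), from 9.66 to 75.2 FPKM. TNFRSF6B was 8.14-fold higher (6.95 to 9.57) and STK40 was 5.43-fold higher (5.10 to 5.79).

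Because so many extreme genes were absent from 1 library, a second ranking was added after the values were seen. It took protein-coding genes with at least 1 FPKM in both libraries, outside the heart muscle lists and the mitochondrial chromosome. The lowest was IER2 (chromosome 19, 13150415 to 13154908), with 59.6 and 9.17 FPKM, a log2 ratio of -2.57. LGALS1, which encodes galectin-1, had 1049.7 and 193 FPKM (log2 ratio -2.44). GLIS2 (-2.27), CDKN1A (-2.20), HECTD3 (-2.19), MXD4 (-2.19), GBA2 (-2.08), PRR5-ARHGAP8 (-2.07), FAM89B (-2.06), LYPLA2 (-2.04) and PRF1 (-2.03) were among those that followed. PRR5-ARHGAP8 is a read-through gene that overlaps others and is uncertain for that reason. At the upper end this ranking added ZNF282 (log2 ratio 1.84) and STMN3 (1.75).

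The remaining SF3b subunits did not share the lower level of PHF5A. The log2 ratios were 0.17 for SF3B1, 0.35 for SF3B2, 0.17 for SF3B3, 0.14 for SF3B4, 0.51 for SF3B5 and 0.54 for SF3B6, each above the median of the expressed genes. With TPM rescaling those of SF3B1, SF3B2, SF3B3 and SF3B4 lay below 0, between -0.28 and -0.03, and still above that scale's median. DDX42 had a log2 ratio of -0.08, and DDX46 was below 1 FPKM in both libraries. With PHF5A included, the 8 expressed members of the SF3b list lay at the 91.7 percentile, inside the central 95% of random lists. The 12 expressed partners of SF3b in SF3a and the U2 snRNP had a median 0.47 above that of the expressed genes, at the 99.1 percentile of 10000 random lists of equal size and matched expression. SF3A2 was 2.10-fold higher by CPM (interval 2.04 to 2.17) and SF1 1.57-fold higher. The 24 other snRNP proteins had a median 0.29 above the expressed genes (percentile 97.7), although LSM4 (log2 ratio -1.18), SNRNP200 (-0.82) and PRPF4 (-0.80) were lower. Among genes of at least 5 FPKM both lists fell inside the central 95% of random lists, at the percentiles 94 and 94.8. The median of 10 SR proteins was at the 10.1 percentile, with SRSF6 at -0.82. The CLK and DYRK kinases (percentile 48.6), hnRNP proteins (52.1), nonsense-mediated decay factors (36.1) and known targets of that decay (86.2) stayed inside the central range of random lists, but with TPM rescaling the decay targets lay outside it at 98.0.

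Of the 40 lists, 5 had a median above the central 95% of their random lists and 5 below it, where 2 in all are expected if genes vary independently. Genes of a list can vary together, so more lists than that could fall outside by chance. The highest was the integrated stress response, whose 21 expressed members had a median 0.75 above the expressed genes (percentile 100). Of these, 7 were at least 2-fold higher and 0 at least 2-fold lower. With TPM rescaling 5 were higher and 1 lower, and the percentile stayed at 100. TRIB3 (chromosome 20, 362835 to 397559) had 18.7 and 70.4 FPKM, 3.77-fold higher by CPM (interval 3.6 to 3.95). PCK2 was 4.46-fold higher (4.07 to 4.90), PSAT1 3.26-fold (2.91 to 3.66) and CHAC1 3.40-fold (2.99 to 3.88). The 20 genes of the unfolded protein response lay 0.30 above the expressed genes (percentile 98.7), with HSP90B1 at 0.84 and HSPA5 at 0.69, and none reached 2-fold. Among genes of at least 5 FPKM their percentile was 96.2, inside the central range. Cytosolic chaperones were at the 93.8 percentile. The 24 immediate early genes lay 0.37 above the expressed genes (percentile 99.5) but went both ways: KLF2 (2.84), JUN (1.89) and EGR1 (1.89) were higher and IER2 (-2.57) was lower. Their percentile was 81.9 among genes of at least 5 FPKM. As deposited 4 of them were at least 2-fold higher and 1 lower, and with TPM rescaling 3 and 3.

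**Figure D2:**
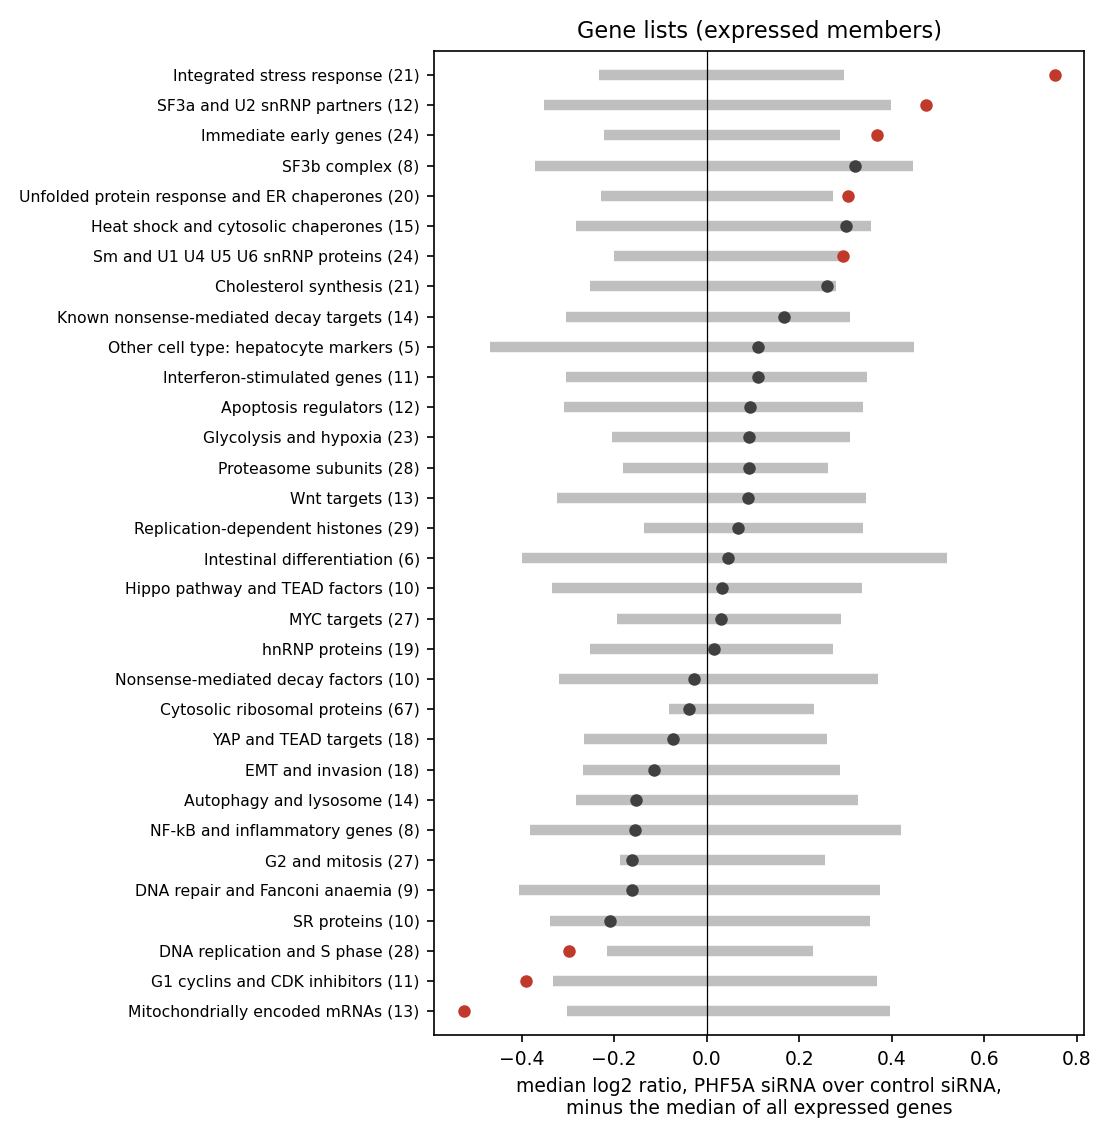
Points give the median log2 ratio of each reported gene list with at least 5 expressed members, minus the median of all expressed genes, with the number of members in parentheses; grey bars span the central 95% of 10000 random lists matched on expression, and red points lie outside it. The integrated stress response lies farthest above 0 (0.75) and the mitochondrially encoded mRNAs farthest below it (-0.52).

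Several cell-cycle genes were lower. CDKN1A (chromosome 6, 36676460 to 36687339), which encodes the cell-cycle inhibitor p21, had 235 and 50.6 FPKM and was 4.65-fold lower (interval 4.54 to 4.77). DNA replication genes, 28 in number, had a median -0.30 relative to the expressed genes (percentile 0.4) with none past 2-fold on the FPKM + 1 scale, although with TPM rescaling 6 were at least 2-fold lower. CDC45 (-0.71), MCM5 (-0.71) and FEN1 (-0.70) had the lowest log2 ratios among them. The 27 genes of G2 and mitosis lay at the 4.51 percentile, and at 0.11 among genes of at least 5 FPKM. CDC25B was 3.36-fold lower (3.24 to 3.48) and KIF20A 2.79-fold (2.57 to 3.03). G1 cyclins and CDK inhibitors lay at the 1.25 percentile, at 2.94 with TPM rescaling and at 18.2 among genes of at least 5 FPKM. That list contains CDKN1A and also CCND2, which had 598 and 5 counts and so followed the heart muscle genes. Apoptosis regulators were at the 69.3 percentile, with BIRC5 at -1.08 and BAK1 at 0.90. DNA repair genes were at 24.2.

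Among the TEAD transcription factors, the DNA-binding partners of YAP, TEAD2 and TEAD3 were lower. TEAD2 (chromosome 19, 49340595 to 49362457) had 10.3 and 3.92 FPKM, 2.62-fold lower (interval 2.37 to 2.91). TEAD3 (chromosome 6, 35473597 to 35497076) had 21.2 and 8.25 FPKM, 2.58-fold lower (2.35 to 2.82). TEAD1 (-0.13) and TEAD4 (-0.10) had log2 ratios near the median of the expressed genes. LATS2 was 4.23-fold higher (3.69 to 4.87). The Hippo list (percentile 57.6) and the YAP and TEAD targets (28.3) did not stand apart. ANKRD1, the lowest YAP target, is also on a heart muscle list. KDM3A was under 1 FPKM in both libraries, with 173 and 39 counts, a ratio of 0.231 (0.159 to 0.329). Wnt targets lay at the 71.9 percentile with MYC at 0.78, and MYC targets at 48.3 with NOP56 at -1.11. The PAF1 complex, with 3 expressed members, lay at 87.4 and the chromatin genes linked to KDM3A, also 3, at 73.0.

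Genes of epithelial-mesenchymal transition (EMT) and invasion were at the 17.7 percentile, with 4 of 18 at least 2-fold lower. PLAU, the urokinase gene, had 64.9 and 15.3 FPKM, a log2 ratio of -2.02. SPARC (621 and 16 counts) and CDH2 (382 and 1) were nearly absent from the knockdown library, as many heart muscle genes were, and VIM (549 and 36) had a ratio of 0.0672 (interval 0.0466 to 0.0942). COL3A1 on the fibroblast list behaved likewise, with 959 and 31 counts, while COL1A1 had 1362 and 786. These were the 2 expressed fibroblast markers (percentile 0.89). With TPM rescaling the list had 3 members and lay inside the central range, at 7.3. Interferon-stimulated genes went both ways, with IFI6 at -1.29, OASL at -1.23 and IRF7 at 1.10. Their median was 0.11 above the expressed genes (percentile 73.5), but among the 4 members of at least 5 FPKM it was -0.61 relative to them (percentile 2.6). NF-kB genes were at the 19.2 percentile with TNFAIP2 at -1.25. Intestinal differentiation genes were at 47.7 with CDX2 at -0.93.

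The housekeeping lists here stayed inside the central range of random lists as wholes, with cholesterol synthesis farthest from the expressed genes (0.26 above). The 67 cytosolic ribosomal proteins had a median at the 7.79 percentile. RPL4 (-1.46), RPS7 (-1.26), RPSA (-1.15) and RPS3 (-1.05) were at least 2-fold lower. These values are uncertain because reads may be shared with their pseudogenes, which was not tested. After median centring 2 of the 67 were at least 2-fold lower, and with TPM rescaling 12. Proteasome subunits (68.2), glycolysis and hypoxia genes (61.8), autophagy and lysosome genes (12.4), histones (38.6) and cholesterol synthesis (96.7) stayed inside the central range. Within them SLC2A1 had 122 and 43.6 FPKM, PFKP had 142 and 67.9, PFKL had 12.1 and 26.2, and SREBF2 had 56.5 and 19.6. Hepatocyte markers were at the 69.2 percentile. Blood (CD68, -0.38), neural (TUBB3, 0.69) and keratinocyte or breast markers (KRT10, -0.23) had 1 expressed member each.

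Since PHF5A acts in splicing, ratios were also compared by gene structure. Protein-coding genes with more annotated exons had lower median ratios. The median log2 ratio was -0.06 for 190 genes of 1 exon, -0.09 for 1187 genes of 2 to 4, and -0.12 for 2581 genes of 5 to 9. It was -0.18 for 2576 genes of 10 to 19 and -0.26 for 1143 genes of 20 or more. The last lay below each of its 10000 random lists (percentile 0). The difference between 20 or more exons and 1 to 4 exons was -0.18, with a bootstrap interval over genes of -0.22 to -0.13, which treats genes as independent although they are not replicates. That gap is small beside the SD of 0.63 over genes. The share of genes at least 2-fold lower showed no steady trend. It was 8.42% for 1 exon, 5.39% for 5 to 9 and 7.0% for 20 or more. The share at least 2-fold higher fell from 5.26% for 1 exon to 0.175% for 20 or more. Mean intron length showed no steady trend, with medians from -0.19 to -0.13 over quintiles of the genes. By GC content, the quintile with the most GC had a median of -0.05 (percentile 100) and the next-to-lowest quintile -0.22 (percentile 0). Expressed antisense RNAs, 280 in number, had a median of 0.12, and 237 long intergenic RNAs had 0.06. Antisense values are uncertain because the strand setting of the counting is not given in the sources used here.

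**Figure D3:**
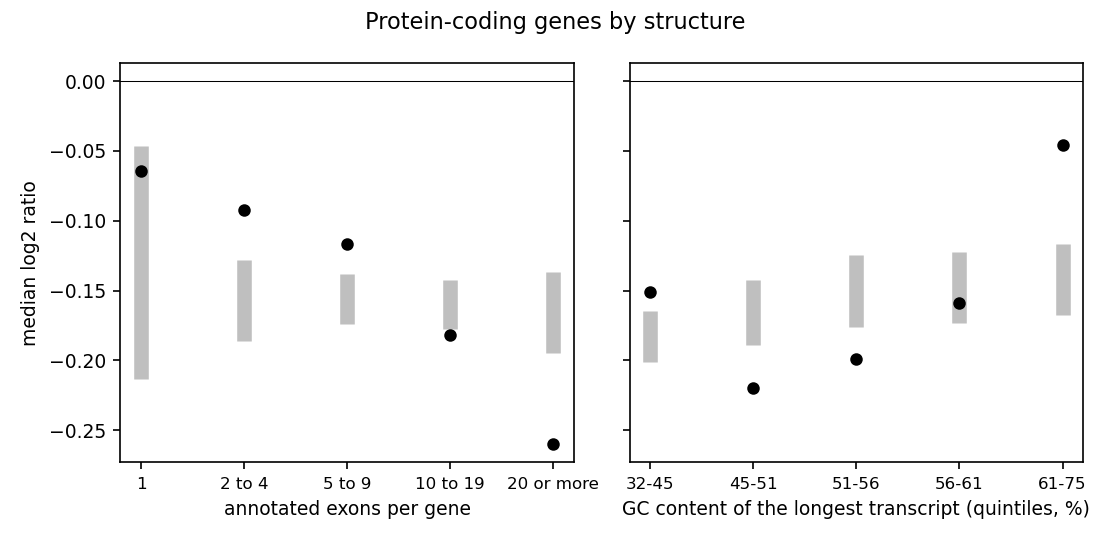
Points give the median log2 ratio, knockdown over control, of protein-coding genes by number of annotated exons (left) and by quintiles of transcript GC content in percent (right); grey bars span the central 95% of random gene lists matched on expression. The median goes from -0.06 for 1 exon to -0.26 for 20 or more.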

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

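No paired analysis was possible because there was 1 library per group. Leaving out the heart muscle genes, and TPM rescaling of the median, the gene lists and single named genes, were chosen after the values were seen. The numbers of genes at least 2-fold higher and lower were 227 and 555. With a pseudocount of 0.1 they were 469 and 1129, with a minimum of 5 FPKM 131 and 309, with median centring 345 and 358, and with TPM rescaling 107 and 1405. A 1.5-fold threshold gave 757 and 1631, CPM with a prior of 0.5 gave 628 and 2100, and protein-coding genes alone gave 148 higher. The filter, the threshold and the gene class change these numbers by construction, and a smaller pseudocount admits more low genes. The CPM setting changed the measure together with the prior, and the cause of its shift was not tested. TPM scaling lowers the ratios because the summed FPKM, to which abundant short RNAs add much, is larger in the knockdown library. Without the heart muscle genes the numbers were 227 and 506.

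PHF5A stayed lower throughout, with a log2 ratio of -1.61 as deposited and -1.98 with TPM rescaling. The median of the expressed genes was -0.15, but -0.19 with a pseudocount of 0.1 and -0.47 with TPM rescaling. The difference between 20 or more and 1 to 4 exons was -0.18, and grew in size to -0.27 at a minimum of 5 FPKM and to -0.24 with a pseudocount of 0.1; the cause was not tested.

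Relative to random lists, the quintile with the shortest mean introns went from -0.036 to 0.0068 and the quintile with the least GC from 0.032 to -0.072 at a minimum of 5 FPKM, so these small differences depend on the filter; the cause was not tested. Of 37 gene lists with a value at that minimum, 4 moved by more than the margin of their random lists, among them the PAF1 complex, G2 and mitosis, and interferon-stimulated genes, the last from 0.11 to -0.61 relative to the centre. The PAF1 complex, with 1 member left, went from 0.37 to -0.37. At that minimum the U2 partners, the other snRNP proteins, the unfolded protein response, the immediate early genes and the G1 list came inside the central range of random lists, G2 and mitosis came outside it, and the integrated stress response stayed at percentile 100. With TPM rescaling or removal of heart muscle genes, 0 of 40 lists moved by that margin relative to the centre, though with TPM the decay targets came outside the central range and the G1 list and the fibroblast markers inside it. Centring cannot change these relative values. Removal of heart muscle genes could hardly change them either. Of the expressed list members, 1 of the YAP and TEAD targets was on the heart muscle lists and 0 of any other list. Members nearly absent from the knockdown library but not on the heart muscle lists, such as CCND2, SPARC and CDH2, stayed in. With a pseudocount of 0.1 it was 1 of 40, the fibroblast markers. Named genes with at least a 2-fold difference kept their direction with a pseudocount of 0.1, centring and TPM rescaling. Their sizes were less stable. Over all entries picked for naming, the shift with TPM rescaling passed the margin of the counting interval for 140 and not for 36. With centring these numbers were 101 and 75, and with a pseudocount of 0.1 they were 61 and 115. Depth limits genes under a few counts, and the absence of replicates limits each difference.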

Other observations

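The tests on markers of unrelated tissues and fibroblasts, on overlapping or identical genes and on entries nearly absent from the knockdown library were chosen after the results were seen, as was the pathway search. The other tests were specified before their result was known, on patterns already noticed in these libraries.

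Heart muscle transcripts were abundant in the control library and close to absent in the knockdown library. In a list of 48 such genes, written after their values were seen, 44 were at least 10-fold lower in the knockdown library, which only restates the pattern. A second list of 37 heart muscle genes was written before its values were looked up. Of its 27 members with at least 20 control counts, 12 (44.4%, exact interval 25.5% to 64.7%) were at least 10-fold lower, and 24 had a log2 ratio below the median of the expressed genes. If RNA of heart muscle cells were the source, at least 80% had been predicted, and under 50% had been set as counting against it. The share met that second bound, but the interval includes 50%. Requiring an interval to lie below its bound, here and for the unrelated tissues below, was decided after the values had been computed, so by the bounds as first worded both tests went against their source. Members such as ATP2A2 (6352 and 4057 counts) and KCNH2 (1082 and 1078) are expressed by the knockdown HCT116 cells too, which would hide a small addition. Others, such as TBX5 (100 and 0 counts) and LMOD2 (85 and 0), followed the first list. The heart muscle genes with the most counts in the control library were TTN (65612 counts), MYH7 (10058) and ACTC1 (9182), while MYL2 had 159 and MB 100. Of 12 liver, blood and neural markers with at least 20 control counts, 1 (8.33%, exact interval 0.211% to 38.5%) was at least 10-fold lower. Several, such as ALB (1243 and 1176 counts), are present in both libraries and would hide a small addition, so RNA of further tissues stays open. Of 6 fibroblast markers with at least 20 control counts, 4 were at least 10-fold lower, COL3A1 (959 and 31) and COL1A2 (352 and 7) among them. Of 249 entries with at least 50 control counts that were at least 20-fold lower, 48 were on the heart muscle lists. After summing with overlapping entries, 30 differed by under 2-fold. TNNT2 was among them, with 1049 and 13 counts alone and 5039 and 4305 summed. Where the neighbours hold many counts, such a sum can hide a real change. A further 170 were not on the heart muscle lists, overlapped no gene of them and stayed at least 2-fold lower after summing with overlapping entries. COL4A2 (840 and 5 counts) and IGFBP5 (736 and 6) were among these, named after their values were seen. The lists are not complete, and some of the 170 are genes of heart muscle too, such as GJA1 (433 and 0) and LRRC10 (118 and 0), so this number does not count genes foreign to heart muscle. RNA of heart tissue or of other cells in the control library, by carry-over between libraries or a mixed sample, may explain part of the pattern. It cannot be told apart from an effect of the PHF5A knockdown on a heart-like programme in these cells, which was not tested, because each group is 1 library.

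Genes with 20 or more exons had a median log2 ratio that differed by -0.18 from that of genes with 1 to 4. Within deciles of GC content the difference was -0.18 (bootstrap interval -0.22 to -0.13), or 101% of the original, and negative in 9 of 10 deciles, so GC content is argued against as the whole source. Within deciles of gene length it was -0.11 (interval -0.18 to -0.05), or 61.7% of the original, and negative in 8 of 8 deciles that held at least 20 genes of each class. Gene length may thus account for part of it. A weaker output of genes with many introns when an SF3b subunit is low is a biological candidate, which gene-level values cannot test, and a difference in RNA integrity between the libraries also stays open as untested.

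Of 17 entries at least 20-fold higher in the knockdown library with at least 50 counts, 8 (47.1%) differed by under 2-fold once their counts were summed with overlapping or identical genes. RABL6 is an example, with 2 entries that had 2464 and 1487 counts and 0 and 866. HIST2H2AA3 is another. For these, a different assignment of reads between entries may explain the change. Others stayed at least 2-fold higher: EPDR1 with its neighbours had 9 and 183 counts, and SERPINI1, with no overlapping entry, had 0 and 60. RIMBP3B, TMEM200B and MT-ND4 also stayed higher. The rest turned round and were at least 2-fold lower in the knockdown library after summing. These were RMRP (log2 ratio -1.55), MT-ATP8 (-3.46), C18orf32 (-1.03) and ISY1-RAB43 (-1.03). For entries whose neighbours hold many counts, the sum can hide a real change, so the explanations cannot be told apart there.

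A search of 247 KEGG pathways with at least 10 expressed genes, each set against 2000 random lists, found 41 medians below the central 95% of those lists and 2 above it, where 6.18 are expected in each tail. Pathways share genes, so these are not independent, and genes of a pathway can vary together, which the expected number leaves out. ECM-receptor interaction (34 genes) had a median log2 ratio of -0.66 with 8 genes at least 2-fold lower and 0 on the heart muscle lists, though collagen genes such as COL4A1 (544 and 3 counts) were nearly absent from the knockdown library too. Focal adhesion (106 genes) had -0.39 with 17 lower and 2 higher, and 4 of its genes were on the heart muscle lists; the cell cycle (76 genes) had -0.37 with 6 lower and 0 on those lists, although CCND2 (598 and 5 counts) followed the same pattern. The pathway of hypertrophic cardiomyopathy (39 genes) had -0.95 with 18 lower, and 15 of its genes were on the heart muscle lists.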
